A study of Arabidopsis thaliana with 22 samples.

How the data were processed

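Total RNA from whole inflorescences of Arabidopsis was measured on 22 2-colour Agilent arrays, each with RNA of treated and of mock-treated plants of 1 line. Per the labels, the plants were about 4 weeks old, grown at 20 C, their flowers had been synchronised with 10 uM dexamethasone, and 500 ng of RNA was labelled. The lines carry a dexamethasone-induced microRNA against AP3 (8 arrays), an ethanol-induced one against AP3 (10 arrays) or an ethanol-induced one against AG (4 arrays). The treated sample was in Cy5 on 4, 4 and 2 arrays and in Cy3 on 4, 6 and 2. Groups, comparisons, alternatives, gene lists and the rule for named genes were set before the data were examined.

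The authors extracted the signals with Agilent Feature Extraction 10.5.1. The median and background signals and the processed signals are in units of intensity per the file headers. The log ratio columns are log10 ratios per the file headers, and the deposited value table is a log10 ratio turned to treated over mock in all 22 columns, with medians of 0. The spot flags are 0 or 1 per the file headers. The comparisons used the median signals, since spot means were not among the deposited columns.

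Signals were background corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3). Other tools were statmod 1.5.0, the data.table package (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9. Of 45210 spots 1425 control spots were left out, and spots with an outlier flag were set to missing. Probes were kept when well above background in either channel on at least 4 arrays and with a value in each line and dye orientation. Spots were averaged to 43635 probes and probes to genes by gene code; 36953 probes named 28327 genes, 27785 of which matched the reference annotation table. In all 22918 genes were tested, 22715 matched and 9537 with a symbol of their own; 3968 had several probes. Probes for genomic regions (6049) and gene predictions (633) were tested apart.

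Ethanol amiAP3 replicates 7 and 10, from different slides, correlated at 0.965 over genes (highest of the other pairs within a line, 0.821). The SD of their difference was 0.0967, where spot noise alone gave 0.0767 (12 probes with 11 spots each) and other pairs gave 0.147 to 0.545. They were averaged, so the fit held 21 replicates in place of the 22 arrays of the design. The linear model had a treatment coefficient and a dye intercept for each line, with 15 residual and 2.57 prior degrees of freedom. Differences between lines were contrasts of the treatment coefficients in the same fit. P-values are moderated t-tests of limma, adjusted after Benjamini and Hochberg over all genes tested, with a threshold of 0.05. They rest on the spread between arrays labelled as biological replicates, of which each gene has 1 estimate shared by the 3 lines. Where 1 line varied more between its arrays than the others, its SE and p-values are therefore too small, and where it varied less, too large. Values with ± are named as SD over replicates or SE of the fit. Where 1 sample was not above background on any array of a line, the fold is given as a bound ("at least").

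Genes named in the text are AP3, PI and AG in every line, members of the gene lists by group, the 12 largest changes each way per line and the 6 largest each way per contrast, among genes past the threshold with a symbol and the same direction in all arrays (all but 1 in lines of 8 or more). The text does not print every gene that this rule gives. The 18 lists were floral homeotic MADS-box genes, reported targets of B-class proteins, of AG and of AP1, stamen and anther, carpel and ovule, late pollen, meristem and boundary, gibberellin, auxin, jasmonate with wound and touch, pathogen response, hypoxia and fermentation, heat shock, cell cycle, photosynthesis, circadian clock, and epidermis. They held 302 members, 290 of them measured. Lists were tested with camera (preset correlation 0.01) on the 22084 genes without missing values, adjusted over 90 tests, and again with an estimated correlation, which called 0 of the 90 in place of 28 (lowest adjusted p = 0.142); fry called 36. The list tests thus held 34 of 40 measured photosynthesis genes, 22 of 23 stamen and anther, 14 of 15 auxin, 9 of 10 heat shock and 6 of 7 epidermis genes. Counts and medians used all measured members. Members were also adjusted over their list alone. The tests of the target lists took no account of the direction reported for each target.

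Per channel 55.8% to 71.5% of spots were well above background, 0 were saturated, and 3 to 588 per array had an outlier flag. Median backgrounds were 13 to 42.5. The scripts were tested on simulated data of the same size (22084 independent genes, 21 replicates, 50 changed genes per fold). At 1.25-fold 68% (dexamethasone amiAP3), 76% (ethanol amiAP3) and 54% (ethanol amiAG) of changed genes were recovered, and at 1.5-fold 98%, 94% and 86%; 4.7%, 4.2% and 3.5% of the calls were false. For the differences between lines 85.5% (dexamethasone against ethanol amiAP3) and 81.3% (amiAG against amiAP3) of all changed genes were recovered, with 4.5% and 5% false. Of simulated lists of 25 genes the 1 shifted by 1.25-fold was called, and 0 of 53 other tests, by camera. The simulated genes had the same spread in all lines and no slide effect, whereas arrays of 1 slide correlated at 0.156 in the data. These shares of false calls therefore do not carry over to the data.

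Alternatives were a further threshold of 1.5-fold, Agilent's processed signals, the deposited value table, no background correction, Aquantile scaling between arrays, median centring in place of loess, no filter on dim probes or a strict one, the brightest probe per gene, a common dye term or none, eBayes with trend and robust settings, each line alone, slide or replicate number as a block, list tests by fry or without AP3 and AG (chosen after the data were seen), and each array left out. Permutation tests of correlations over arrays were exact. Up to 100 regroupings of the arrays were drawn for each count.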

Results

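The series holds 22 arrays of the 2-colour type. Each array compared total RNA of whole inflorescences from plants in which an artificial microRNA had been induced with RNA from mock-treated plants of the same line. The plants carried a floral induction system, in which dexamethasone activates an AP1-GR fusion protein and many flowers then develop in step. In 8 arrays a dexamethasone-driven system produced a microRNA against AP3 (dexamethasone amiAP3). In 10 arrays an ethanol-driven system produced the microRNA against AP3 (ethanol amiAP3), and in 4 arrays an ethanol-driven system produced one against AG (ethanol amiAG). AP3 encodes a B-class MADS-domain protein needed for petals and stamens, and AG encodes the C-class protein needed for stamens, carpels and the end of growth of the floral meristem. The labels give no time points. They name no line treated in the same way without an artificial microRNA, and each slide holds arrays of 1 line only. All 4 ethanol amiAG arrays lie on 1 slide, so line and slide cannot be told apart there. Between 55.8% and 71.5% of the spots of a channel were well above background, with median signals of 55 to 138 in Cy3 and 93.5 to 241 in Cy5. The number of arrays per line limits the precision of all values. Ethanol amiAP3 replicates 7 and 10 differed by about the noise between spots and were counted as 1 replicate, which left 9 replicates in that line and 21 in all.

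The first question was whether each microRNA lowered its target. AP3 (AT3G54340) fell to 22.4% of the mock level in the dexamethasone amiAP3 line, with a log2 ratio of -2.16 ± 0.62 (SD, n = 8, lower in 8 of 8 arrays, adjusted p = 2.42e-08). In the ethanol amiAP3 line AP3 fell by 2.51 ± 0.21 (log2, SD, n = 9, lower in 9 of 9 replicates, adjusted p = 9.71e-10), which is 17.5% of mock. AG (AT4G18960) fell by 2.06 ± 0.07 (log2, SD, n = 4, lower in 4 of 4, adjusted p = 5.00e-09) in the ethanol amiAG line, which is 23.9% of mock. AG did not pass the threshold in either amiAP3 line, with log2 ratios of 0.10 (dexamethasone, adjusted p = 0.670) and -0.05 (ethanol, adjusted p = 0.727), and AP3 had -0.15 (adjusted p = 0.601) in the amiAG line. PI (AT5G20240), the B-class partner of AP3, fell by 0.66 in ethanol amiAP3 (log2, adjusted p = 1.74e-06, lower in 9 of 9). In dexamethasone amiAP3 PI fell by 0.35 (adjusted p = 0.00909, lower in 7 of 8 arrays), and in ethanol amiAG by 0.26 (adjusted p = 0.0382, lower in 4 of 4). The call of PI in dexamethasone amiAP3 ended under median centring, when the line was fitted alone and without a dye term. Under median centring PI was at -0.02, where the median of all genes was 0.16. Its call in ethanol amiAG ended under median centring, in the fit of the line alone, without a dye term, with slide as a block, and without replicate 1 (-0.17), replicate 2 (-0.27) or replicate 4 (-0.26).

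In the dexamethasone amiAP3 line a small set of genes rose strongly. The expansin genes EXPA2 and EXPA8, whose proteins loosen cell walls, rose by 4.21 ± 0.30 (log2, SE, higher on 7 of 7 arrays with a value, adjusted p = 2.29e-07) and 1.87 ± 0.09 (higher on 8 of 8, adjusted p = 3.39e-10). MIR319a, a precursor of the microRNA that targets TCP growth regulators, rose by 2.92 ± 0.27 (8 of 8, adjusted p = 3.91e-06). The homeobox genes WOX14 (1.70) and WOX10 (1.04), the transcription factor gene NAC1 (1.35), the RNA-binding protein gene PUM11 (1.22), FMO (1.42), LCD (1.03), the phosphate exporter PHO1 (0.97) and the sugar transporter STP1 (1.75) rose too. The mock signal of EXPA2 was above background on 2 of 8 arrays, that of MIR319a on 4 and that of PUM11 on 3, so their ratios are imprecise. Chosen after their values were seen, the 3 genes without a symbol that rose most were AT4G14819 (5.12), AT5G26290 (4.54, imprecise too, its mock signal being above background on 3 of 8 arrays) and AT3G05640 (3.81). Besides AP3, the largest falls among genes with a symbol were in the cold-responsive KIN2 (-1.04), the receptor kinase gene GSO2 (-0.998), the metal transporter genes ZIP6 (-0.95) and HMA4 (-0.81), LBD20 (-0.89), the invertase gene cwINV4 (-0.88), PRP2 (-0.77), GSTU20 (-0.75), PGL5 (-0.74), the anther gene ATA20 (-0.72) and the storage protein gene VSP1 (-0.72). AT3G23840, without a symbol and chosen after its value was seen, fell by more than KIN2 (-1.297).

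In all 391 of 22918 genes changed in this line (212 higher, 179 lower), 83 of them by at least 1.5-fold. Among genes of flower identity the MADS-box list of 16 measured genes had 1 that rose, SEP3 (0.39), and 2 that fell, AP3 and PI. Adjusted over the list alone 3 rose and 3 fell, and the list as a whole did not pass (adjusted p = 0.904). Of 8 reported B-class targets, 0 rose and 2 fell, again AP3 and PI (1 and 2 adjusted over the list alone; list adjusted p = 0.0636, and 0.677 without AP3; in fry 3.67e-04 and 0.5264). The 40 photosynthesis genes held 2 that fell, PSBO2 (-0.36) and the Rubisco activase gene RCA (-0.26), and 18 adjusted over the list alone. Their median was -0.18 (adjusted p = 1.62e-15, and 0.142 with an estimated correlation). Under median centring it was 0.07 and the call ended. The median of all genes was 0.16 in that setting, so the photosynthesis median still lay below it. Meristem and boundary genes had a median of 0.10 (24 genes, adjusted p = 1.09e-04; adjusted p = 0.226 with an estimated correlation), with CUC3 (0.33) the 1 member that rose, 9 higher and 2 lower adjusted over the list alone. Cell cycle genes had a median of 0.07 (23 genes, adjusted p = 0.0174; adjusted p = 0.572 with an estimated correlation), with 0 members past the threshold and 1 adjusted over the list alone. The jasmonate, wound and touch list (19 genes, median -0.12, adjusted p = 0.0109; adjusted p = 0.317 with an estimated correlation) and the heat shock list (10 genes, median -0.09, adjusted p = 0.0412; adjusted p = 0.504 with an estimated correlation) had 0 members past the threshold, also adjusted over the list alone. The jasmonate median was 0.03 under median centring, also below the 0.16 of all genes there. The heat shock call ended with no filter on dim probes and with a strict one. The mean of the heat shock list was -0.69 in replicate 1 and between -0.18 and 0.23 in the other 7 arrays. In fry the cell cycle, jasmonate and heat shock lists did not pass in this line (adjusted p = 0.249, 0.0619 and 0.231).

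Of 23 stamen and anther genes in this line, 2 rose, ROXY1 (0.17) and ROXY2 (0.38), and 0 fell, while 4 rose and 4 fell adjusted over the list alone. The list's median was -0.24 without passing (adjusted p = 0.224), and its mean ran from -0.75 to 0.39 over the 8 arrays. The carpel list had 2 genes that rose, ALC (0.37) and SPT (0.20), 2 adjusted over the list alone (21 genes, adjusted p = 0.0789). Single members rose in the auxin list, IAA2 (0.96), and in the gibberellin list, GAI (0.27), 1 in each also adjusted over the list alone, and neither list passed (adjusted p = 0.959 and 0.845). Defence genes of the pathogen list did not pass (8 genes, 0 changed, 1 higher adjusted over the list alone, median -0.13, adjusted p = 0.428), nor did the hypoxia list (17 genes, 0 changed, also adjusted over the list alone, adjusted p = 0.0839). For the lists with 0 changed members, limma called 3336 genes at an unadjusted p under 0.05 in this line as a whole. The count of 391 was 60 when the line was fitted alone, 154 with slide as a block, 741 without slide 1, 212 under median centring (141 higher, 66.5%, against 54.2% in the fit reported here), 958 without background correction (348 higher, 36.3%), 719 with Agilent's processed signals (324 higher, 45.1%), and 250, 210 and 186 without replicate 1, 4 or 7. Median centring ended the calls of KIN2, GSO2, HMA4, PRP2, GSTU20, PGL5, ATA20, VSP1, GAI, SPT, ROXY1, PSBO2 and RCA, and the fit of the line alone those of WOX14, WOX10, NAC1, PUM11, STP1, SEP3, ALC, CUC3, ROXY2, GSO2, LBD20, cwINV4, PRP2, GSTU20, ATA20, VSP1, GAI, SPT, ROXY1, PSBO2 and RCA. Slide as a block ended those of STP1, LBD20, cwINV4, PRP2, GSTU20, ATA20, VSP1, CUC3, SPT, ROXY1 and PSBO2, and leaving out slide 1 those of STP1, LBD20, cwINV4, PRP2, GSTU20, ATA20, VSP1, SPT and ROXY2. Agilent's processed signals and the deposited values ended those of LBD20, cwINV4 and ATA20. The calls of LBD20, GSTU20, ATA20 and VSP1 ended with no filter on dim probes and with a common dye term or none, and that of SPT with either dye setting. Those of ATA20, SPT and RCA ended with the brightest probe, and those of ROXY1 and PSBO2 without a dye term. Without replicate 1, 4 or 7, in this order, the calls of STP1 (1.54, 1.599, 1.67), LBD20 (-0.76, -0.86, -0.65), cwINV4 (-0.81, -0.77, -0.71), PRP2 (-0.67, -0.70, -0.75), GSTU20 (-0.61, -0.78, -0.74), ATA20 (-0.61, -0.68, -0.73), VSP1 (-0.65, -0.78, -0.71), SPT (0.17, 0.19, 0.19) and ROXY1 (0.14, 0.18, 0.17) ended. So did ROXY2 without replicate 1 (0.31) or 7 (0.34) and CUC3 without replicate 4 (0.33) or 7 (0.32). Other single arrays ended those of LBD20, GSTU20, ATA20, VSP1, SPT, ROXY1 and CUC3 as well.

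In the ethanol amiAP3 line genes of defence against pathogens rose most. PR1, a marker of the salicylic acid response, rose by 5.13 ± 0.44 (log2, SE, higher in 9 of 9 replicates, adjusted p = 4.86e-07), and PR5 by 4.01 ± 0.19 (9 of 9, adjusted p = 3.40e-10); the mock signal of PR1 was above background on 4 of 10 arrays. The glutathione transferase gene GSTF2 (3.75), the chitinase gene CHI (3.59) and the glucanase genes BG3 (3.45) and BGL2 (also PR2, 2.81) followed. Further rises were in GRP3S (2.80), SAG21 (2.70), the MADS-box gene AGL86 (2.68), the histone gene HIS1-3 (2.42), NAC036 (2.32) and PCC1 (2.31). After AP3, the largest falls among genes with a symbol were in the latex-protein-like genes MLP34 (-1.83) and MLP328 (-1.71), GSTU20 (-1.75), the sugar transporter SWEET10 (-1.56), PGL5 (-1.54), the amylase gene BAM5 (-1.32) and VSP1 (-1.297). UF3GT (-1.53), GSTF12 (-1.18), LDOX (-1.17) and TT7 (-1.15), which act in anthocyanin and flavonoid formation, fell too. In this line 6164 of 22918 genes changed (3190 higher, 2974 lower), 662 of them by at least 1.5-fold.

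By group, 7 of 8 measured pathogen response genes rose in ethanol amiAP3 and 0 fell (7 and 0 adjusted over the list alone; median 1.39, adjusted p = 7.65e-10; adjusted p = 0.142 with an estimated correlation). Among them were the regulators PAD4 (2.13), EDS1 (0.58) and WRKY70 (0.65) and the salicylic acid synthesis gene SID2 (0.59), and the 1 that did not pass was NIMIN1 (0.17). Of 17 genes of hypoxia and fermentation 6 rose (6 adjusted over the list alone), among them the haemoglobin gene HB1 (1.57), the alcohol dehydrogenase gene ADH1 (0.73) and LBD41 (0.46), with a median of 0.11 (adjusted p = 0.00359; adjusted p = 0.373 with an estimated correlation). Cell cycle genes moved the other way: 17 of 23 fell and 0 rose (18 fell adjusted over the list alone; median -0.31, adjusted p = 7.83e-11; adjusted p = 0.203 with an estimated correlation). Among them were the cyclin gene CYCB1;2 (-0.74), the cytokinesis gene KN (-0.66), AUR1 (-0.58) and CDC20.1 (-0.56); PCNA1 (-0.08) and MCM5 (0.07) did not pass. Of 40 photosynthesis genes 19 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.18 (adjusted p = 6.63e-05; adjusted p = 0.386 with an estimated correlation). The Rubisco subunit genes RBCS3B (-0.66) and RBCS2B (-0.52) fell and the antenna gene LHCB1.3 (0.28) rose. In the jasmonate, wound and touch list 8 of 19 rose and 1 fell, the same numbers adjusted over the list alone (median 0.23, adjusted p = 0.0145; adjusted p = 0.353 with an estimated correlation). The touch genes TCH3 (1.18) and TCH4 (1.17), ZAT10 (1.01) and JAZ1 (0.83) rose and the jasmonate synthesis gene LOX2 (-0.67) fell. Clock genes had 3 of 10 that rose, ELF4 (0.35), PRR7 (0.39) and GI (0.35), 4 adjusted over the list alone (median 0.19, adjusted p = 0.0309; adjusted p = 0.426 with an estimated correlation). This call ended with the strict filter on dim probes.

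Several floral regulators changed in ethanol amiAP3 within lists that did not pass as a whole in camera. In fry 4 of the lists that camera did not call there passed: the B-class targets (adjusted p = 7.77e-07, and 0.00306 without AP3), the gibberellin list (3.67e-04; 3 of 10 rose, 4 rose and 1 fell adjusted over the list alone), the floral MADS-box list (0.00531, and 0.613 without AP3 and AG) and the AG targets (0.00880). Of 8 reported B-class targets 4 fell and 2 rose (5 and 2 adjusted over the list alone; adjusted p = 0.0754, and 0.436 without AP3, which is 1 of the 4), with BNQ1 at -0.37 and NAP at 1.299. In ethanol amiAG, where AP3 did not pass, 5 of these 8 fell and 2 rose, the same numbers adjusted over the list alone (adjusted p = 0.111). The highest member reached 1.305 there. Directions reported for single targets were not taken into account, so these counts do not show an effect of AP3. Of 23 stamen and anther genes 5 fell and 0 rose (5 adjusted over the list alone; adjusted p = 0.178), among them the early anther regulators SPL (-0.42) and TDF1 (-0.50). In replicates 7 and 10, averaged, the mean of this list was -1.32, against -0.17 to 0.49 in the other 8; without both, 5279 genes changed and the call of TDF1 ended. Of 24 meristem and boundary genes 4 rose and 8 fell (5 and 9 adjusted over the list alone; adjusted p = 0.364), with STM at 0.43, WUS at -0.38 and CUC3 at -0.46. Of 15 reported AP1 targets 2 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.602), with TEM1 at 0.67 and FD at 0.46. The carpel list had 3 that rose and 4 that fell (4 and 5 adjusted over the list alone; adjusted p = 0.978), with ALC at 0.49 and ETT at 0.41, and the floral MADS-box list had 3 and 5 (4 and 5 adjusted over the list alone; adjusted p = 0.449), with AGL6 at 0.27. Auxin, epidermis and heat shock lists showed few changes: 2 rose and 2 fell, 1 and 1, and 2 and 1 (2 and 2, 2 and 1, and 2 and 1 adjusted over the list alone; adjusted p = 0.904, 0.602 and 0.431), with GH3.5 at 0.52, YUC1 at -0.26, GL2 at -0.29, GOLS1 at 0.71 and HSP90.1 at 0.33. The count of 6164 was 9639 with Agilent's processed signals (3881 higher, 40.3%, against 51.8% in the fit reported here), 9423 without background correction, 1105 under median centring (733 higher, 66.3%) and 3973 without replicate 9. Median centring ended the calls of UF3GT, GSTF12, LDOX, TT7, WRKY70, LBD41, LHCB1.3, LOX2, SPL, TDF1, STM, WUS, FD, ALC, ETT, AGL6, GH3.5, YUC1, HSP90.1 and the 3 clock genes. Slide as a block ended those of TDF1, ELF4 and HSP90.1, and a common dye term or none that of WRKY70. Leaving out replicate 9 ended those of UF3GT (-1.25), LDOX (-0.86), LHCB1.3 (0.20), GH3.5 (0.38), TDF1 (-0.52) and HSP90.1 (0.29). Replicate 4 ended those of ELF4 (0.29), GI (0.27), TDF1 (-0.45) and HSP90.1 (0.31), and replicate 3 those of WRKY70 (0.57) and TDF1 (-0.47). Replicate 8 ended those of LDOX (-0.98) and TDF1 (-0.46), replicate 2 those of TDF1 (-0.47) and HSP90.1 (0.27), and replicate 1 that of HSP90.1 (0.31).

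In the ethanol amiAG line defence genes were again among the largest rises. PCC1 rose by 4.52 ± 0.39 (log2, SE, higher in 4 of 4 replicates, adjusted p = 4.46e-07), BG3 by 4.34 ± 0.47 (4 of 4, adjusted p = 3.27e-06) and GSTF2 by 3.95. LURP1 (3.84), PR5 (3.62), AGL86 (3.47), CHI (2.93), DMR6 (2.85), ERF15 (2.73) and the genes of the NPR1-interacting proteins NIMIN-2 (3.31) and NIMIN1 (2.74) rose as well. PR1 was at least 7.28-fold higher (adjusted p = 0.00199), its mock signal being above background on 0 of 4 arrays. Without replicate 1 its call ended (fitted log2 2.17). The largest falls among genes with a symbol were in the lectin gene JAL23 (-3.33), the myo-inositol oxygenase genes MIOX4 (-3.04) and MIOX2 (-2.67), BT5 (-2.98), BAM5 (-2.89), PGL5 (-2.76), the proline dehydrogenase gene ERD5 (-2.64), MLP328 (-2.53), MLP34 (-2.47), DIN10 (-2.44) and PGIP2 (-2.28). BSMT1, which makes methyl esters of salicylic and benzoic acid, was at least 8.29-fold lower (adjusted p = 1.72e-05). In this line 7592 of 22918 genes changed (3754 higher, 3838 lower), 1823 of them by at least 1.5-fold. With slide as a block 5154 of the 7592 kept their call and direction.

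By group, 8 of 8 pathogen response genes rose in ethanol amiAG, 8 also adjusted over the list alone (median 2.36, adjusted p = 1.86e-08; adjusted p = 0.142 with an estimated correlation), with PAD4 at 2.58, WRKY70 at 1.93 and EDS1 at 0.89. Of 17 hypoxia and fermentation genes 7 rose (7 adjusted over the list alone; median 0.28, adjusted p = 0.00544; adjusted p = 0.386 with an estimated correlation), with HB1 at 2.16, ADH1 at 1.07 and the pyruvate decarboxylase gene PDC2 at 0.53. Cell cycle genes fell in 15 of 23 cases (15 adjusted over the list alone; median -0.63, adjusted p = 7.48e-09; adjusted p = 0.226 with an estimated correlation), with CYCB1;2 at -1.20, KN at -0.99, AUR1 at -0.95 and CDC20.1 at -0.92, and PCNA1 at -0.02 without passing. Photosynthesis genes fell in 27 of 40 cases (31 adjusted over the list alone; median -0.40, adjusted p = 5.36e-11; adjusted p = 0.187 with an estimated correlation), with RBCS3B and RBCS2B both at -1.25 and LHCB1.2 at -1.06. Of 13 reported AG targets 6 fell and 1 rose, the same numbers adjusted over the list alone (median -0.14, adjusted p = 0.0231; adjusted p = 0.226 with an estimated correlation). In ethanol amiAP3, where AG did not pass, 5 of the 13 fell and 1 rose (5 and 2 adjusted over the list alone; median -0.10, adjusted p = 0.135). Members that fell in ethanol amiAG were the gibberellin synthesis gene GA3OX1 (-0.74), the stamen boundary gene SUP (-0.64), SPL (-0.59), WUS (-0.45) and the carpel gene CRC (-0.33). Since reported directions were not taken into account, these falls are not by themselves a response to loss of AG.

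Other groups did not pass as a whole in camera in ethanol amiAG. In fry, which asks whether members move 1 way on balance and not whether they differ from other genes, 6 of them passed. These were the B-class target (adjusted p = 5.41e-05), floral MADS-box (7.26e-04, and 0.0796 without AP3 and AG), meristem (0.00779), auxin (0.0195), late pollen (0.0214) and gibberellin (0.0356) lists. In the jasmonate, wound and touch list 7 of 19 rose and 5 fell, the same numbers adjusted over the list alone (adjusted p = 0.759), with WRKY33 at 1.48, TCH4 at 1.16, JAZ5 at -1.24 and LOX2 at -1.41. Of 11 late pollen genes 4 fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 0.0733), with VGD1 at -1.13, ANX2 at -0.44 and TUA1 at 0.75. The gibberellin list had 3 of 10 that rose and 2 that fell (3 and 3 adjusted over the list alone; adjusted p = 0.723), with the receptor gene GID1B at 0.55. The auxin list had 2 that rose and 5 that fell (3 and 6 adjusted over the list alone; adjusted p = 0.504), with the auxin synthesis gene TAA1 at -0.85. Meristem and boundary genes had 2 that rose and 8 that fell, the same numbers adjusted over the list alone (adjusted p = 0.0636), with CUC3 at -0.77 and STM at 0.41. AP1 targets had 5 that rose and 3 that fell, the same numbers adjusted over the list alone (adjusted p = 0.586), with TFL1 at 0.70, TEM1 at 0.72 and AGL24 at -0.38. The floral MADS-box list had 1 that rose and 5 that fell, the same numbers adjusted over the list alone (adjusted p = 0.143), with CAL at -0.34 and TT16 at -0.40. In the clock list 1 gene rose, ELF4 (1.03; 1 adjusted over the list alone; adjusted p = 0.700). The count of 7592 was 3075 under median centring (772 higher, 25.1%, against 49.4% in the fit reported here), 4476 without replicate 1 and 3995 without replicate 2. Median centring ended the calls of WUS, CRC, ADH1, PDC2, TCH4, TEM1, STM, GID1B, TUA1 and ANX2. The fit of the line alone ended those of TCH4, TEM1, GID1B, VGD1 and ANX2, slide as a block those of DIN10, WUS, CRC, TCH4 and TEM1, and no filter on dim probes that of CRC. Leaving out replicate 1 ended those of DIN10 (-1.98), WUS (-0.40), CRC (-0.41), TCH4 (0.97), TEM1 (0.46) and GID1B (0.26). Replicate 2 ended those of DIN10 (-2.06), WUS (-0.41), CRC (-0.32), GID1B (0.47), ANX2 (-0.33) and AGL24 (-0.31). Replicate 3 ended those of WUS (-0.51), CRC (-0.26) and ANX2 (-0.23), and replicate 4 those of WUS (-0.49), CRC (-0.34), TCH4 (0.58) and TEM1 (0.54).

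**Figure D1:**
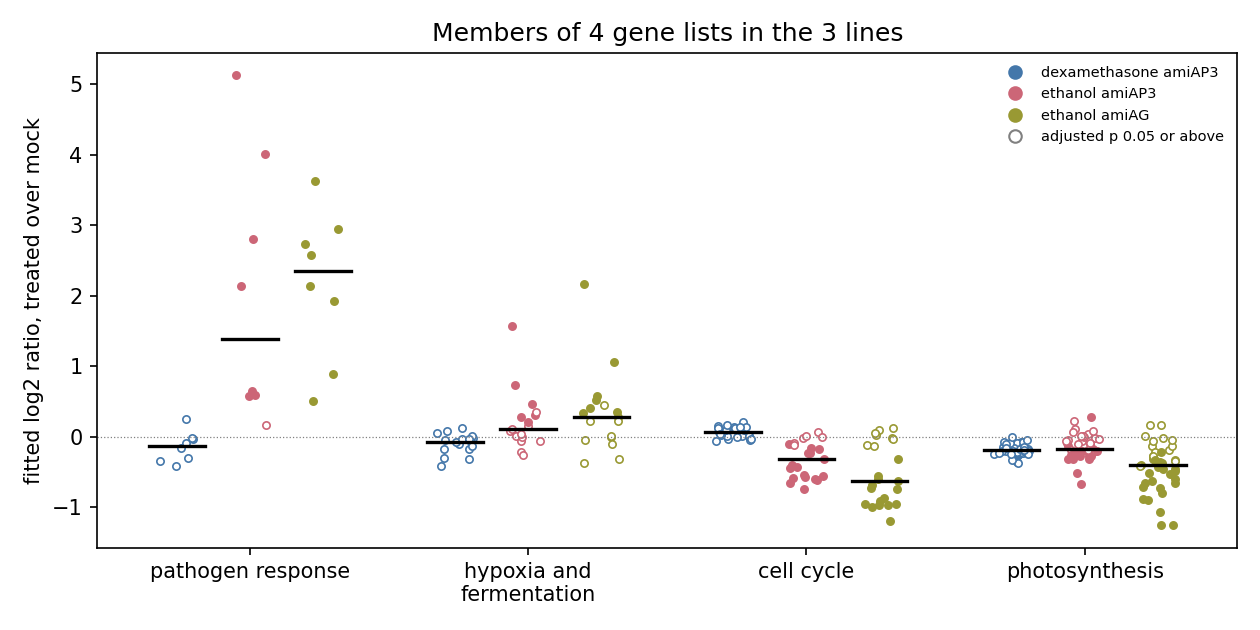
Fitted log2 ratio (treated over mock) of each measured member of 4 gene lists in the 3 lines; filled points passed the threshold, open points did not, and bars are list medians. The pathogen response medians were -0.13, 1.39 and 2.36 in dexamethasone amiAP3, ethanol amiAP3 and ethanol amiAG. PR1 in the last is drawn at its fitted value. The photosynthesis median of dexamethasone amiAP3 was -0.18, and 0.07 under median centring, where the median of all genes was 0.16.

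The next comparison set both amiAP3 lines against each other, which share the target and differ in the inducer. Higher in dexamethasone amiAP3 were the expansin genes EXPA2 (difference of log2 ratios 4.22 ± 0.40, SE, adjusted p = 7.53e-06) and EXPA8 (1.89), MIR319a (2.41), WOX14 (1.81), SWEET10 (1.78) and UF3GT (1.94). SWEET10 and UF3GT differed because of their fall in the ethanol line, to -1.56 and -1.53, against 0.23 and 0.40 in the dexamethasone line. Lower in dexamethasone amiAP3 were PR1 (-5.15 ± 0.63, SE, adjusted p = 7.02e-05, though its signal in the dexamethasone line was above background on at most 1 of 8 arrays), PR5 (-4.31), GSTF2 (-4.03), CHI (-3.83), BG3 (-3.67) and BGL2 (-3.23). In all 3055 of 22918 genes differed (1534 higher and 1521 lower in dexamethasone amiAP3), 670 of them by at least 1.5-fold. Of the pathogen response list 7 of 8 were lower, 7 also adjusted over the list alone (median difference -1.57, adjusted p = 2.27e-10; adjusted p = 0.142 with an estimated correlation), PAD4 by -2.15. Cell cycle genes were higher in 14 of 23 cases (15 adjusted over the list alone; median 0.44, adjusted p = 1.16e-11; adjusted p = 0.187 with an estimated correlation), with CYCB1;2 at 0.89 and KN at 0.79. Lower too were 6 of 19 jasmonate, wound and touch genes (7 lower and 1 higher adjusted over the list alone; median -0.35, adjusted p = 1.78e-04; adjusted p = 0.187 with an estimated correlation), with TCH3 at -1.21. The hypoxia list had 5 of 17 lower (6 adjusted over the list alone; median -0.23, adjusted p = 3.84e-04; adjusted p = 0.260 with an estimated correlation), with HB1 at -1.75 and ADH1 at -1.04. Meristem and boundary genes had 7 of 24 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.14, adjusted p = 0.0105; adjusted p = 0.417 with an estimated correlation), with CUC3 at 0.79. The clock list had 2 of 10 lower (2 adjusted over the list alone; median -0.24, adjusted p = 0.0304; adjusted p = 0.426 with an estimated correlation). The count of 3055 was 6496 without background correction (2687 higher, 41.4%, against 50.2% in the fit reported here), 6458 with Agilent's processed signals (3566 higher, 55.2%), 1575 with slide as a block, 1019 with replicate number as a block, and 856 under median centring (571 higher, 66.7%). Median centring also ended the hypoxia and clock calls and that of ADH1. The count was 5279 without slide 1 of the dexamethasone line and 1964 without ethanol amiAP3 replicate 9. The AG target and gibberellin lists, which camera did not call, passed in fry (adjusted p = 0.0208 and 0.0356); the gibberellin median was 0.011 and its mean -0.10. The call of UF3GT ended under median centring, with a common dye term or none, in fits of each line alone, with slide as a block and when any of 11 single arrays was left out, for example ethanol amiAP3 replicate 9 (1.66).

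The last comparison set the amiAG line against the amiAP3 line under the same inducer. AP3 was higher by 2.36 and AG lower by 2.02 in ethanol amiAG, as their own ratios give. Further genes higher in ethanol amiAG were NIMIN1 by 2.57 ± 0.21 (SE, adjusted p = 2.52e-06), WRKY54 by 2.33, PCC1 by 2.21, NIMIN-2 by 2.12 and WRKY38 by 1.89. The pathogen response list did not pass (2 of 8 higher; 3 higher and 1 lower adjusted over the list alone; median difference 0.11, adjusted p = 0.103; adjusted p = 0.572 with an estimated correlation). Lower in ethanol amiAG were ERD5 (-2.58 ± 0.66, SE, adjusted p = 0.0420), MIOX4 (-2.45), JAL23 (-2.42), BSMT1 (-2.13, with its treated signal at the floor) and the aldolase gene FBA5 (-1.64). In all 653 of 22918 genes differed (338 higher, 315 lower in ethanol amiAG), 240 of them by at least 1.5-fold. Photosynthesis genes were lower in 9 of 40 cases (20 adjusted over the list alone; median difference -0.23, adjusted p = 6.63e-12; adjusted p = 0.187 with an estimated correlation), with LHCB1.2 at -1.06. Of 13 AG targets GA3OX1 (-0.64) and SUP (-0.45) were lower, 2 also adjusted over the list alone (median -0.07, adjusted p = 0.0145; adjusted p = 0.210 with an estimated correlation). Cell cycle genes had a median of -0.28 (adjusted p = 6.53e-05; adjusted p = 0.404 with an estimated correlation), with 0 of 23 past the threshold in limma, where 3723 of all genes had an unadjusted p under 0.05, and 1 higher and 11 lower adjusted over the list alone. The meristem list had 2 of 24 lower (3 adjusted over the list alone; median -0.07, adjusted p = 0.0205; adjusted p = 0.426 with an estimated correlation). Gibberellin genes had 1 of 10 lower, GA3OX1 (2 adjusted over the list alone; median -0.09, adjusted p = 0.0480; adjusted p = 0.203 with an estimated correlation), and late pollen genes 0 of 11, also adjusted over the list alone (median -0.16, adjusted p = 0.0145; adjusted p = 0.404 with an estimated correlation). The call of the AG target and late pollen lists ended under median centring, that of the late pollen and gibberellin lists with the strict filter, that of the gibberellin list also with the brightest probe or a common dye term, and that of the meristem list without background correction. In fry the cell cycle, meristem and late pollen lists did not pass (adjusted p = 0.0548, 0.0821 and 0.0548), and the auxin list did (0.0419). The count of 653 was 121 with slide as a block, which ended the calls of ERD5, PCC1, MIOX4 and BSMT1, and 54 under median centring (19 higher, 35.2%, against 51.8% in the fit reported here), which ended those of ERD5, PCC1, BSMT1, GA3OX1, SUP and LHCB1.2. Agilent's processed signals and the deposited values ended the calls of PCC1 (both 1.52) and WRKY38 (1.76 and 1.75), and no background correction that of PCC1 (1.502). The call of ERD5 ended too with no filter on dim probes, with a common dye term or none, and without any 1 of ethanol amiAP3 replicates 1 to 6. The count was 382 without a dye term and 96 without ethanol amiAG replicate 2, which ended the calls of ERD5 (-2.22), PCC1 (2.00), MIOX4 (-2.11), BSMT1 (-1.82), JAL23 (-2.32) and SUP (-0.38). Without replicate 1 those of ERD5 (-2.14), PCC1 (2.03), MIOX4 (-2.20) and BSMT1 (-2.08) ended. Without ethanol amiAP3 replicates 3, 4, 6 or 9 the count was 406, 400, 390 or 1104.

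Across genes, which are not independent replicates, the fitted log2 ratios of both ethanol lines ran together (Pearson r = 0.835, Spearman rho = 0.798, 22918 genes). In both ethanol lines 2330 genes rose, where 523 would be shared by chance. In both 2122 fell, where 498 would by chance, and 24 changed in opposite directions. PR5, BG3, GSTF2 and PCC1 rose and MLP34, MLP328 and PGL5 fell in both. The amiAP3 lines had r = 0.047 (jackknife SD 0.149, rho = 0.018). With replicate number as a block, although the numbers did not pair the arrays, r was 0.546. In that fit the value of each line is set at replicate 1 through replicate effects that the lines share. This makes the line values run together by construction, so that r does not measure agreement. In the fit without that block 46 genes rose in both (30 by chance), 59 fell in both (23 by chance) and 40 went opposite ways. AP3, PI, PGL5, GSTU20 and VSP1 fell in both amiAP3 lines, and ALC rose in both. Of the 46 and 59 genes that rose or fell in both, 74 changed in the same direction in ethanol amiAG. ALC, PI and PGL5 were among the 74, though the calls of ALC (0.056) and PI in ethanol amiAG ended under median centring. Of all 6164 genes that changed in ethanol amiAP3, 4452 changed in the same direction in ethanol amiAG. The count of 74 therefore does not set the genes shared by both amiAP3 lines apart from other ethanol amiAP3 calls. Of the genes shared by both amiAP3 lines 13 also differed between ethanol amiAG and ethanol amiAP3, which need not mean a change particular to amiAP3. PGL5, 1 of the 13, fell further in ethanol amiAG (-2.76 against -1.54). JR1, TSA1, TI2, RCA, HAT9 and AT1G53430 likewise went further the same way there. AP3, AT1G13230, PME1 and AT4G27980 did not pass in ethanol amiAG. AT3G46770 rose in both amiAP3 lines (0.84 and 0.51) and fell in ethanol amiAG (-0.90, adjusted p = 1.30e-04). AT5G02890 fell in both amiAP3 lines (-0.24 and -0.10) and rose in ethanol amiAG (0.12, adjusted p = 0.0300). Genes of the 13 other than PGL5, AP3 and RCA were named after their values were seen. Dexamethasone amiAP3 and ethanol amiAG had r = 0.078 (rho = 0.025), with 104 genes changed in the same and 81 in opposite directions. Of these 32 rose in both (35 by chance), 72 fell in both (30 by chance), 58 rose in the first and fell in the second (36 by chance) and 23 the reverse (29 by chance). Under median centring r was -0.242. The replicate block gave 0.353, which for the same reason does not measure agreement.

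**Figure D2:**
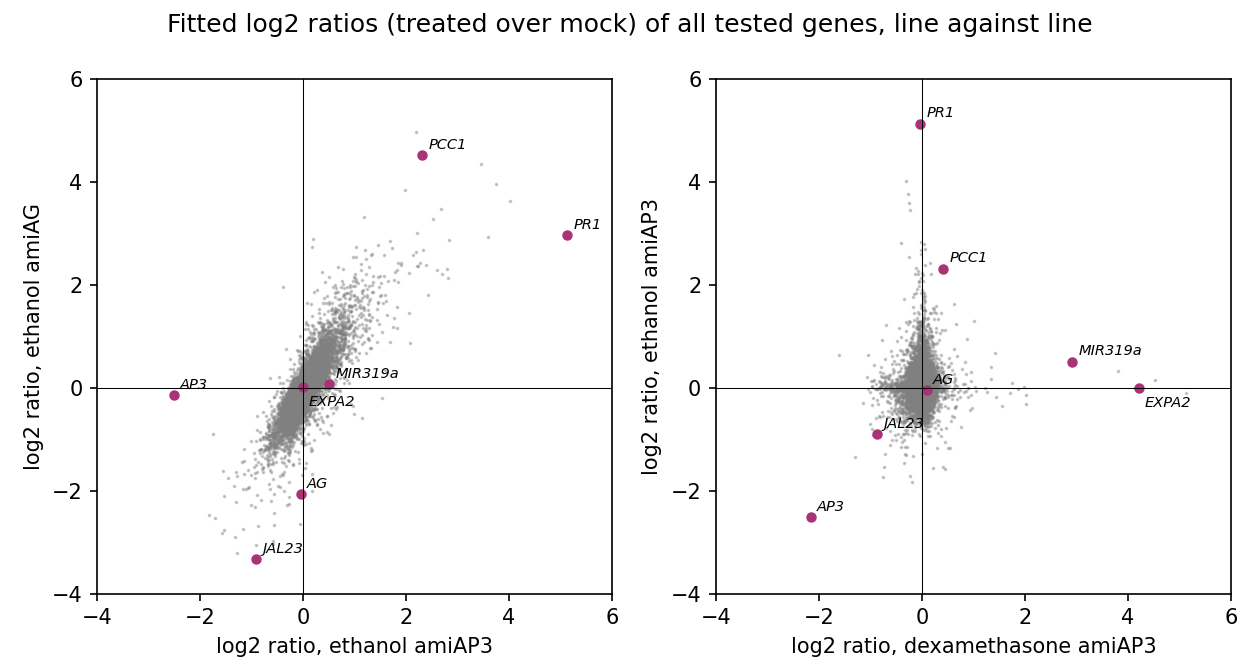
Fitted log2 ratio (treated over mock) of every tested gene in ethanol amiAG against ethanol amiAP3 (left) and in ethanol amiAP3 against dexamethasone amiAP3 (right), with 7 genes named. The cloud lies along a line on the left (r = 0.835) and spreads along both axes on the right (r = 0.047). PR1 in ethanol amiAG is drawn at its fitted value.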

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

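The tests of loss of AP3, of dye bias and of ethanol itself for the defence genes, of dye bias in the 1 remaining gene, of slide, and of how far AP3 fell were chosen after the results were seen. The first pattern was the rise of defence genes in both ethanol lines. The mean log2 ratio of the pathogen response list was 2.00 ± 0.42 (SD, n = 9) in ethanol amiAP3 and 2.17 ± 0.80 (n = 4) in ethanol amiAG, against -0.14 ± 0.20 (n = 8) in dexamethasone amiAP3. Loss of AP3 in itself was argued against: AP3 fell in dexamethasone amiAP3 too, where the upper 95% bound of the list mean was 0.032, far below the mark of 1.002 set from the ethanol amiAP3 mean, though the labels give no treatment times. Dye bias of these probes was argued against, since the lowest list mean of any ethanol replicate of either orientation was 1.251. The ethanol treatment itself (lower list mean 2.00) cannot be told apart from effects of the microRNAs, because no ethanol-treated line without one was labelled.

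The second pattern was a set of 135 genes, 18 of them above 2-fold, that rose in dexamethasone amiAP3 and were higher there than in ethanol amiAP3, where they did not rise. Renewed activation of AP1-GR by dexamethasone stays open. The mean of 13 reported AP1-repressed genes was -0.02, with 95% bounds of -0.10 and 0.06. A mean of -0.20 or lower had been set as the mark of such activation, so by that mark alone the values went against it. But the mark left out SEP3, a reported AP1-activated gene, which rose by 0.39, and the 13 went both ways. The call of SEP3 ended when the line was fitted alone. A gene-specific dye bias alike on all arrays cancels in the fit that picked these genes, which had 4 arrays of each orientation. The test of dye bias was therefore nearly settled by that choice and adds no support. Of the 135 genes 134 were above 0 in both orientations (medians 0.42 and 0.37). The other was AT2G33480 (-0.023 and 0.33), with a fitted value of 0.15. Its lower 95% bound of 0.078 followed from its selection. The call of AT2G33480 ended with Agilent's processed signals, the deposited values, median centring, the brightest probe, a common dye term or none, the line alone, slide as a block, and without slide 1 or replicate 1, 2, 4, 7 or 8. For MIR319a (2.92, against 0.51 with adjusted p = 0.160 in ethanol amiAP3), a probe that reads an artificial microRNA precursor may be the source: over the 8 arrays MIR319a went with AP3 at rho = -0.929 (exact permutation p = 0.00223, adjusted p = 0.00446; r = -0.922, exact permutation p = 0.00186, adjusted p = 0.00372; without the 2 arrays farthest from the median r = -0.812). No other raised gene was set against AP3 in this way. The correlation therefore cannot tell a precursor signal from the strength of the response on each array. In ethanol amiAG MIR319a was at 0.06 (limma adjusted p = 0.923). A precursor read alike in all lines would raise MIR319a in both ethanol lines too, where it did not pass the threshold. The ethanol lines thus lend this source no support, and whether the precursors of the lines differ was not tested. No biological explanation of the remaining genes was tested.

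The third pattern was the spread between arrays of dexamethasone amiAP3, 56.7% of which lay on 1 component. Arrays of 1 slide were more alike by 0.267 in mean correlation, and 16 of 210 regroupings (a share of 0.076) gave as much, which leaves slide open. A share of floral stages or tissues that differs between arrays may contribute: the SD over arrays of the stamen list (0.29) and the photosynthesis list (0.14) reached percentile 100 of random lists, which were not matched for co-expression, while the late pollen list (0.10) reached 86 and the carpel list (0.06) 70.3. How far AP3 fell also stays open (rho = -0.714, exact permutation p = 0.0576; r = -0.529, exact permutation p = 0.184; without the 2 arrays farthest from the median r = -0.565).

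Regroupings of the arrays were compared for each count on the 22084 genes without missing values. For dexamethasone amiAP3 chance cannot be excluded: the real arrays gave 377 genes, 3 of 35 regroupings, the real one included as in all such counts here, gave as many, and the highest other gave 1520. That regrouping set replicates 1 and 2, both of slide 1, against the rest, which points to a structure of the samples; with slide as a block 154 genes changed and without slide 1 741. For ethanol amiAP3 chance is unlikely (5903, 1 of 100, highest other 4272, which set replicate 5 against the rest). For ethanol amiAG the 3 regroupings are too few (7302, 1 of 3, highest other 0, where limma called 9636 genes at an unadjusted p under 0.05 in the real arrangement). Chance is also unlikely for the difference between dexamethasone and ethanol amiAP3 (2908, 1 of 100, highest other 1173) and between ethanol amiAG and ethanol amiAP3 (642, 1 of 100, highest other 336). These regroupings moved arrays between slides, each of which holds 1 line, so a slide effect is not excluded; with slide as a block 1575 and 121 genes differed.

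Of 248 groups of replicates, 17 held 1 replicate far from the others, where chance gives about 1 in 20. In dexamethasone amiAP3 these were the list means of the cell cycle in replicate 2 (-0.13), floral MADS-box genes in replicate 7 (-0.29) and heat shock in replicate 1 (-0.69), and RCA in replicate 3 (0.21). In ethanol amiAP3 they were the means of the stamen and anther list (-1.32) and the AG targets (-0.47) in replicates 7 and 10, averaged, heat shock in replicate 2 (0.52) and late pollen in replicate 8 (-0.24). In ethanol amiAG they were AG in replicate 4 (-1.96), the clock list in replicate 3 (-0.22), the meristem list in replicate 1 (0.004), PGL5 (-3.46) and STM (0.60) in replicate 1, PCNA1 (0.36) and AT4G14819 (-0.46) in replicate 3, ALC in replicate 2 (0.14) and HSP18.2 in replicate 4 (-0.015).

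Between dexamethasone and ethanol amiAP3 3055 genes differed by the test of the contrast. List medians differed for the cell cycle (0.44), clock (-0.24), hypoxia (-0.23), jasmonate (-0.35), meristem (0.14) and pathogen response (-1.57) lists. With an estimated correlation 0 of these 6 passed in camera (adjusted p from 0.142 to 0.426), and median centring ended the hypoxia and clock calls. Genes that differed were EXPA2 (4.22), MIR319a (2.41), UF3GT (1.94), EXPA8 (1.89), WOX14 (1.81), SWEET10 (1.78), CYCB1;2 (0.89), KN (0.79), CUC3 (0.79), PR1 (-5.15, no exact difference, since its dexamethasone-line signal was above background on at most 1 of 8 arrays), PR5 (-4.31), GSTF2 (-4.03), CHI (-3.83), BG3 (-3.67), BGL2 (-3.23), PAD4 (-2.15), HB1 (-1.75), TCH3 (-1.21) and ADH1 (-1.04). Between ethanol amiAG and ethanol amiAP3 653 genes differed. List medians differed for AG targets (-0.072), cell cycle (-0.28), gibberellin (-0.086), late pollen (-0.16), meristem (-0.073) and photosynthesis (-0.23) genes. With an estimated correlation 0 of these 6 passed in camera (adjusted p from 0.187 to 0.426), and median centring ended the AG target and late pollen calls. Genes that differed were NIMIN1 (2.57), AP3 (2.36), WRKY54 (2.33), PCC1 (2.21), NIMIN-2 (2.12), WRKY38 (1.89), ERD5 (-2.58), MIOX4 (-2.45), JAL23 (-2.42), BSMT1 (-2.13, no exact difference, since its treated signal was above background on 0 of 4 arrays in ethanol amiAG), AG (-2.02), FBA5 (-1.64), LHCB1.2 (-1.06), RBCS2B (-0.74, a call that ended without ethanol amiAG replicate 1, at -0.62, replicate 2, at -0.67, or replicate 4, at -0.80, without any of ethanol amiAP3 replicates 1 to 6, and with Agilent's processed signals, the deposited values, no background correction, median centring, no filter on dim probes, no dye term or each line alone), GA3OX1 (-0.64) and SUP (-0.45). Slide as a block ended the calls of UF3GT, ERD5, PCC1, MIOX4, BSMT1 and RBCS2B.

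Probes for genomic regions, which no gene comparison used, changed in 2, 44 and 109 of 1468 cases in dexamethasone amiAP3, ethanol amiAP3 and ethanol amiAG.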

How the results depend on the processing

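The fit without slide 1 and the one without ethanol amiAP3 replicates 7 and 10 were chosen after the data were seen. Of 5086 values of named genes under the alternatives, 4726 kept direction and side of the threshold, 343 lost the call, 17 gained one and 0 turned. Median centring ended 64 of 229, each line alone 33, slide as a block 30 and single arrays left out 151 of 1962. Under median centring the median of all genes was 0.16 in dexamethasone amiAP3 and -0.16 in ethanol amiAG. Aquantile scaling leaves ratios unchanged by construction.

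In the order dexamethasone amiAP3, ethanol amiAP3, ethanol amiAG, dexamethasone against ethanol amiAP3 and amiAG against amiAP3 the counts were 391, 6164, 7592, 3055 and 653. A threshold of 1.5-fold left 83, 662 and 1823, fewer by construction. Median centring gave 212, 1105, 3075, 856 and 54. Agilent's processed signals gave 719, 9639 and, for the first contrast, 6458, the deposited values 706, 9634 and 6466, and no background correction 958, 9423 and 6496. Without a dye term the first line had 260 and the last contrast 382; with each line alone these were 60 and 990. Slide as a block gave 154 in the first line and 1575 and 121 in the contrasts. Without slide 1 the first line had 741 and the first contrast 5279. Replicate numbers did not pair the arrays (1 of 16 pairs correlated best with its own number), and as a block they gave 1019 and 258 in the contrasts. The cause of these shifts was not tested. Without replicates 7 and 10 of ethanol amiAP3 5279 genes changed there.

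With single arrays left out the counts ran from 186 to 583, 3973 to 6191, 3995 to 6794, 1964 to 4452 and 96 to 1104. The first was 250, 210 and 186 without replicates 1, 4 and 7, the second 3973 without replicate 9, the third 4476 and 3995 without replicates 1 and 2. The first contrast had 1964 without ethanol amiAP3 replicate 9. The last had 96 without ethanol amiAG replicate 2, and 406, 400, 390 and 1104 without ethanol amiAP3 replicates 3, 4, 6 and 9.

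AP3 and AG kept their fall under all alternatives, with -2.28 to -2.02, -2.55 to -2.47 and -2.10 to -2.03 when single arrays were left out. The correlation of the lines was -0.061 to 0.094 (both amiAP3 lines), 0.789 to 0.842 (both ethanol lines) and 0 to 0.109 (dexamethasone amiAP3 and ethanol amiAG) in those fits. The last was -0.242 under median centring, and the cause was not tested. With the replicate block it was 0.353, and 0.546 for the amiAP3 lines. That block sets each line's value at replicate 1 through shared replicate effects. Both values therefore rise by construction and do not measure agreement. List calls numbered 24 to 31 with single arrays left out, and 0 in camera with an estimated correlation. Between 55.8% and 71.5% of spots above background limits what dim genes can show.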

Other observations

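Of 178 probes for gene predictions 6 rose and 5 fell in ethanol amiAP3, 10 rose and 14 fell in ethanol amiAG, and 0 changed in dexamethasone amiAP3, where limma called 3336 of all genes at an unadjusted p under 0.05. Region probes that changed were higher in 19 and lower in 25 cases in ethanol amiAP3, and higher in 41 and lower in 68 in ethanol amiAG.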
